A study of Homo sapiens with 6 samples.

How the data were processed

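Bulk RNA sequencing was done on MDA-MB-231-D3H2LN cells, here called MDA231-LN, an established human breast cancer cell line derived from MDA-MB-231. Per the labels' protocols, JAG1 was knocked out with Cas9 protein and a pair of guide RNAs aimed at separate places in a single exon, and single-cell clones were isolated. The 6 libraries fall into 2 groups of 3. In the control group the knockout cells carried an empty lentiviral vector, and in the rescue group they carried a lentiviral vector with human JAG1. The virus was made in HEK293T packaging cells. RNA was extracted with a column kit, and libraries were made by a sequencing service and sequenced in pairs with 150 bases, per the labels' protocols. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

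The deposited table holds counts of read pairs per gene, not normalized, made by the authors with featureCounts 2.0.1 and the Ensembl release 105 annotation of GRCh38, per the file headers. STAR, Subread and DESeq2 are also named, without versions, per the submitters' processing notes. The aligner's settings and any read trimming are not given in the sources used here. Per the file headers, the command counted pairs over whole gene spans, introns included, and set no option for strand, for pairs that overlap several genes or for pairs that align to several places. With that tool's defaults, such pairs were left out and strand was ignored. This affects the measurements, because a gene that lies inside another gene loses its reads. Of 19878 protein-coding genes in the table, 2372 lie to at least 99% inside other genes, and 2207 of these had 0 counts in all libraries. Among the 12459 protein-coding genes with under 10% of their span inside another gene, 1811 had 0 counts. A count of 0 for a gene inside another is therefore no measurement of its level, and values of partly overlapped genes are uncertain. Values of genes with near-identical copies, such as HLA, keratin, histone, heat shock and ribosomal protein genes, are uncertain because pairs that align to several places were left out.

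The table had 61541 genes, of which 61369 (99.7%) were matched to symbols by their identifiers and 58366 (94.8%) to a gene type in GENCODE 29. No row lacked a gene name, and 0 value columns were left unused. A count above 0 in any library was found for 24404 genes. Coordinates are those of the deposited table on GRCh38. Library totals ranged from 15794704 to 19970459 counts, so that 3 counts, taken as the limit that a count of 0 allows, corresponded to between 0.150 and 0.190 CPM (counts scaled by library size) per library. Intervals and limits of this kind cover counting error only, since read pairs without molecular identifiers are not independent molecules.

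The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the counts as deposited, with trimmed mean of M values (TMM) normalization, filterByExpr by group, robust dispersion and group as the only term. Fold changes are the rescue group over the control group, so positive log2 values mean higher with the JAG1 vector. The standard error (SE) of a log2 fold change was its size divided by the square root of the test's F value. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. CPM values use TMM-scaled library sizes and are given as mean ± SD of the 3 libraries. Fitted fold changes of genes with very few counts in one group depend on the prior count. For a gene with 0 counts in a group, the fold is given as a lower bound against 3 counts over that group, and for 1 to 3 counts as a ratio with its 95% counting interval.

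The genes named were chosen by rule. JAG1 came first, followed in every case by JAG2, NOTCH1, NOTCH2, NOTCH3, NOTCH4, HES1, HES4, HEY1, HEYL and NRARP. Then came the 8 largest rises and 8 largest falls among called genes with a mean log2 CPM of at least 1, a symbol that is not a clone or locus identifier and groups that do not overlap. The 6 smallest p-values in each direction among genes with a mean log2 CPM of at least 4 were added, and up to 4 members with the smallest p of each gene list described. Some genes that this rule takes are not reported here. There were 32 gene lists. The 30 lists with at least 4 tested genes were tested with limma's camera (limma 3.58.1) on log2 CPM with a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were alternatives. With an estimated correlation, camera takes its degrees of freedom from the 6 libraries and not from the genes, so few lists can pass. JAG1 was in no list. The groups, tests, gene lists, naming rule and the other settings listed next, except for 2, were fixed before the data were examined.

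The other settings were other normalizations (median-of-ratios size factors, upper quartile, library size only), other filters, DESeq2 1.42.0, limma-voom, non-robust dispersion, the replicate number as a block, leaving out each library in turn, protein-coding genes only, an adjusted p under 0.01 and a test against a fold of 1.2. After the data were seen, 2 more were added. In the first, each gene was offset by the regional median, the median log2 fold change of the 25 tested genes on either side of it on its chromosome. The other kept only genes with under 10% of their span inside another gene. Chromosome medians used the 10599 genes with a mean log2 CPM of at least 2 and were tested by drawing 10000 permutations of the genes, adjusted over 23 chromosomes.

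The replicates were compared before they were averaged. No libraries held identical values, and the chi-square per degree of freedom between libraries of a group was 3.27 to 5.84, against 50.2 to 56.3 between groups. The scripts were tested on simulated data for the comparison of the rescue and control groups, with 14048 genes tested, 195 of them changed. Of genes changed 1.5-fold, 70.1% were recovered, and of genes changed 2-fold, 80.6%, with 8 false calls among 155. In the data 7454 of 14304 tested genes were called, so these rates need not hold there. A shift of 0.5 placed on all genes of chromosome 13 was found as a median of 0.51, and the regional offset lowered the calls on that chromosome from 173 to 1. In that simulation no other difference was placed, so the neighbours shifted alike. In the data, the quartiles of chromosome 13 were 0.38 and 0.77, so the simulation does not show how well the offset works there. Figures were drawn with matplotlib 3.10.9.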

Results

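Gene expression was measured by bulk RNA sequencing in MDA-MB-231-D3H2LN (MDA231-LN) cells, a human triple-negative breast cancer line isolated from a lymph node metastasis. All cells had a knockout of JAG1, which encodes the Notch ligand Jagged-1. The 3 control libraries came from knockout cells with an empty lentiviral vector, and the 3 rescue libraries from knockout cells with a JAG1 vector. Read pairs assigned to genes numbered 16346026, 18414804 and 15794704 in control libraries 1 to 3, and 17067093, 19970459 and 17919734 in rescue libraries 1 to 3. The series concerns the part that tumour cell JAG1 plays in lymph node metastasis, and the comparison asks which genes differ when JAG1 is put back into the knockout. The sample titles also call the rescue JAG1 OE (overexpression), and no library came from cells without the knockout. Whether the vector restored the earlier JAG1 level or exceeded it therefore cannot be told, nor whether a change undoes an effect of the knockout.

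Cells with the JAG1 vector had 7.24-fold more JAG1 RNA and higher levels of the Notch target genes HES1 and NRARP and of the receptor gene NOTCH3. Genes of cholesterol synthesis, of collagens and basement membrane, of antigen presentation, of interferon response and of the unfolded protein response were mostly higher, with 18 of 22, 16 of 25, 14 of 20, 17 of 28 and 18 of 23 tested members up, FDFT1, COL4A1, CD74, BST2 and TRIB3 among them. These lists were called by limma's camera with a preset correlation (adjusted p from 1.30e-07 to 0.00278) and not with an estimated one (adjusted p from 0.313 to 0.343). The estimated version has few degrees of freedom with 6 libraries, so its missing calls decide little on their own. The estimated correlations were 0.249 for cholesterol synthesis, 0.132 for antigen presentation, 0.062 for the unfolded protein response and 0.044 for interferon response. All of these lie above the preset 0.01, while the estimate for collagens was -0.026. Where the estimate lies above the preset, the preset p-values are likely too small. The matrix protein gene SPARC rose from 2.17 ± 0.328 to 334.4 ± 8.69 CPM and the laminin gene LAMA5 from 14.1 ± 1.83 to 419.4 ± 16.1 CPM (mean ± SD, n = 3 per group). The epithelial transcription factor gene EHF, the nucleotide pyrophosphatase gene ENPP1, the co-receptor gene NRP1 and the lymphatic growth factor gene VEGFC fell. Log2 fold changes were -1.21 for NRP1 and -1.78 for VEGFC, and their neighbours on the chromosome were lower too, with medians of -0.42 and -0.73. The neighbours of EHF and ENPP1 had medians of 0.08 and -0.19. In all, 7454 of 14304 tested genes differed between the groups in edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, and genes over long stretches of chromosomes were shifted together, mostly upward on chromosome 13 and mostly downward on chromosomes 4, 6 and 14.

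JAG1 (ENSG00000101384, minus strand of chromosome 20 from 10637684 to 10673999, GRCh38) had 1181, 1241 and 1199 counts in control libraries 1 to 3 and 8675, 10192 and 8991 counts in rescue libraries 1 to 3. Its level was 71.0 ± 4.18 CPM in the controls and 514 ± 4.88 CPM in the rescue libraries (n = 3 each). The log2 fold change was 2.86 (SE 0.05, edgeR adjusted p = 5.17e-34). JAG1 ranked between the percentiles 75.1 and 77.9 of expressed genes in the control libraries, and between 98.2 and 98.3 in the rescue libraries. Counts over the whole gene cannot separate RNA of the edited gene from the coding sequence of the vector, and they do not test whether the edit removed the protein.

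HES1, a transcriptional repressor and direct Notch target, rose from 20.7 ± 1.52 to 45.6 ± 3.39 CPM (log2 fold change 1.14, SE 0.09, edgeR adjusted p = 5.37e-14). NRARP, a Notch-induced feedback inhibitor, rose from 4.17 ± 0.273 to 12.2 ± 2.32 CPM (log2 fold change 1.55, SE 0.17, edgeR adjusted p = 4.72e-10). NOTCH3 rose from 4.09 ± 0.337 to 10.1 ± 0.268 CPM, a log2 fold change of 1.31 (SE 0.17, edgeR adjusted p = 2.09e-08). JAG2, the paralogous ligand gene, fell by 0.79 on the log2 scale (SE 0.10, edgeR adjusted p = 7.83e-09). Its neighbours on chromosome 14 had a median log2 fold change of -0.55, and 60.0% of its span lies inside other genes. NOTCH2 rose by 0.36 (SE 0.11, edgeR adjusted p = 0.0279), but its adjusted p ranged from 1.78e-06 to 0.146 over 18 other settings and missed 0.05 in 6 of them, library size only and the omission of control library 3 (0.131), rescue library 1 (0.0673) or rescue library 2 (0.146) among them. The other panel genes were not called in the main fit. NOTCH1 had a log2 fold change of 0.16 (edgeR adjusted p = 0.0569), HES4 0.29 (0.218), HEY1 0.39 (0.339), HEYL -0.24 (0.389) and NOTCH4 -0.14 (0.812). NOTCH1 was called without control library 1 (edgeR adjusted p = 0.0341) and without rescue library 2 (0.0252; range over 18 other settings 0.0252 to 0.798). HES4 was called with the regional offset, at 0.58 (edgeR adjusted p = 0.0138; range over 18 other settings 0.0138 to 0.565).

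**Figure D1:**
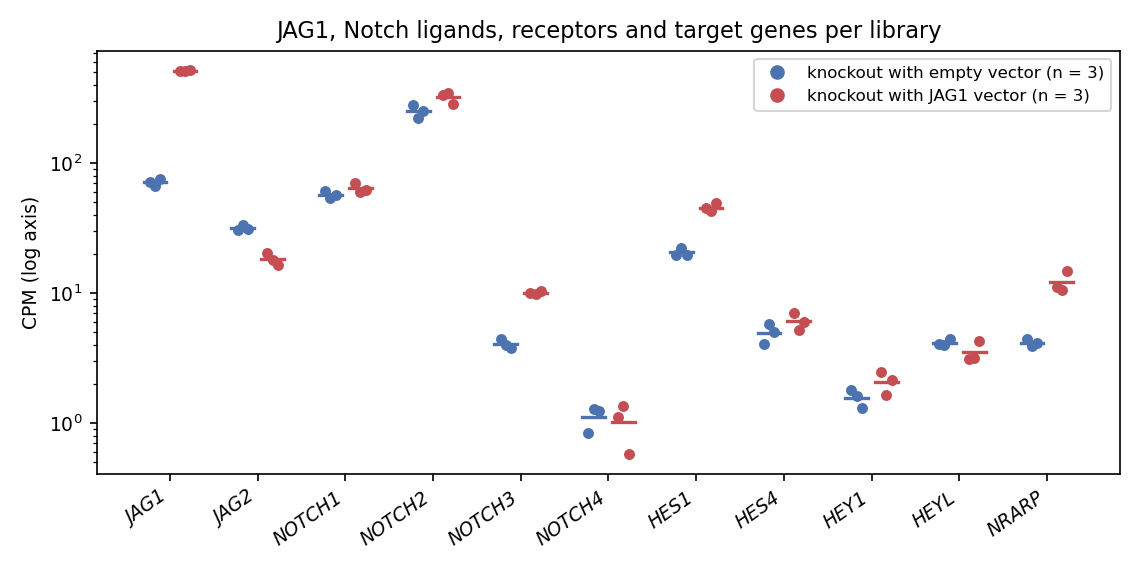
CPM on a log axis of JAG1, JAG2, the 4 NOTCH receptor genes and 5 Notch target genes, with 1 point per library and a line at the mean of 3 libraries for knockout cells with the empty vector (blue) or the JAG1 vector (red). JAG1, NOTCH3, HES1 and NRARP lie higher with the JAG1 vector in all 3 libraries, and JAG2 lies lower.

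Of the Notch target list, 12 genes were tested. Besides HES1, NRARP and NOTCH3, the basic helix-loop-helix repressor gene BHLHE40 rose, with a log2 fold change of 1.56 (SE 0.07, edgeR adjusted p = 1.35e-21), so that 4 members rose, 3 fell and 5 were not called. The members that fell were HES7, ID3 and MYC, named after their values were seen. Of the 6 tested ligand and receptor genes, 2 rose, 1 fell and 3 were not called. Among 26 genes of Notch receptor processing and signalling, 13 rose, 9 fell and 4 were not called. The protease gene ADAM10 rose by 0.74, the fucosyltransferase gene POFUT1 by 0.49 and the glycosyltransferase gene LFNG by 0.99, while RBPJ, the DNA-binding partner of the Notch intracellular domain, fell by 0.97 from 384 ± 12.1 to 196 ± 4.98 CPM. The neighbours of RBPJ on chromosome 4 had a median log2 fold change of -0.59. None of these 3 lists was called by limma's camera (adjusted p = 0.691 for targets, 0.691 for ligands and receptors and 0.599 for processing). With fry, which does not compare a list with other genes, all 3 were called (adjusted p = 0.00563, 0.0157 and 0.00746; range over 17 other settings of the 3 lists 0.00563 to 0.897). Adjusted over the list alone, the counts were the same for targets and processing, and for ligands and receptors 3 rose and 1 fell.

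Across all tested genes, 3787 were higher and 3667 lower in the rescue group, and 1547 changed at least 2-fold, 870 upward and 677 downward (edgeR, adjusted p under 0.05). The 3 libraries of one group did not overlap the 3 of the other for 57.6% of the genes, against 10% by chance, and 7105 of the called genes were among them. Libraries of a group correlated with r of 0.988 to 0.990 in log2 CPM over genes, and libraries of different groups with 0.950 to 0.954. Genes are not independent replicates in these correlations. Rescue library 3 stood apart on the second principal component (8.18% of the variance), at -29.7 against 15.3 and 15.5 for the other rescue libraries. Without it, 7153 genes were called. The first component, with 73.6% of the variance, separated the groups.

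The largest rises included several genes with almost no reads in the control. HR, a nuclear receptor corepressor gene of the hair cycle, had 0 counts in the controls and 661 in the rescue libraries, at least 203-fold higher against 3 counts over the control group. SYT6, which encodes a synaptotagmin, had 1 count against 424, a ratio of 390.04 with a 95% counting interval from 69.6 to 15442. ABI3 had 2 against 415 counts (ratio 191, interval 52.5 to 1581), PAEP, which encodes the secreted protein glycodelin, 2 against 395 (182, interval 49.96 to 1505) and GAL3ST1, a sulfotransferase gene, 2 against 361 (166, interval 45.6 to 1376). IGFN1 went from 6 to 3406 counts (log2 fold change 8.98, SE 0.20) and the glycosyltransferase gene GALNT9 from 5 to 1045 (7.53, SE 0.32). When 1 library was left out, log2 fold changes ran from 6.99 to 11.39 for GALNT9, 7.76 to 10.08 for SYT6, 6.81 to 10.10 for ABI3 and 8.69 to 9.83 for IGFN1. The highest values of GALNT9, SYT6 and IGFN1 were those without control library 2, and that of ABI3 was without control library 1, which held all of its control counts. SPARC rose by 7.25 (SE 0.08, edgeR adjusted p = 3.34e-40), and 38.8% of its span overlaps a gene on the opposite strand. Of these genes, the log2 fold changes of all but SPARC rest on at most 6 control counts.

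The largest falls were in NAA11 (-6.30, SE 0.24), an acetyltransferase gene with 83.7% of its span inside other genes, and in CADM2, a cell adhesion gene, from 16.8 ± 1.36 to 0.264 ± 0.129 CPM (-5.99, SE 0.25, edgeR adjusted p = 1.18e-21). MUSK, the kinase of the neuromuscular junction, fell by 5.09 from 15.3 ± 1.12 to 0.445 ± 0.0657 CPM. EHF fell by 4.39 from 35.8 ± 3.03 to 1.70 ± 0.13 CPM (edgeR adjusted p = 4.30e-25). NLRP2, DACT2, TPRXL and the long noncoding RNA LINC01446 had log2 fold changes of -4.22, -3.96, -3.67 and -3.49. Without rescue library 3 that of LINC01446 was -4.50, and it ran from -4.50 to -2.96 when 1 library was left out. Without rescue library 2 that of DACT2 was -4.56, in a range from -4.56 to -3.69.

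Among genes at higher levels, the smallest p-values for a rise belonged to SPARC, LAMA5, COL4A2, TGM2, COL4A1 and IGFN1. LAMA5, on chromosome 20 from 62307955 to 62367312, rose by 4.89 (SE 0.07, edgeR adjusted p = 8.37e-38). TGM2, a transglutaminase that crosslinks matrix proteins, rose from 424 ± 6.38 to 1688 ± 39.3 CPM (log2 fold change 1.99, SE 0.04, edgeR adjusted p = 2.30e-31). The smallest p-values for a fall belonged to ENPP1, CD96, EHF, NRP1, GPAT2 and the noncoding RNA MANCR, which overlaps other genes over 81.2% of its span. ENPP1, on chromosome 6 from 131808016 to 131895155, fell from 491 ± 10.8 to 149.8 ± 5.12 CPM (log2 fold change -1.71, SE 0.05, edgeR adjusted p = 4.15e-28). CD96, an immunoglobulin-family receptor gene, fell by 2.27, GPAT2, a mitochondrial acyltransferase gene, by 2.05 and MANCR by 1.85.

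**Figure D2:**
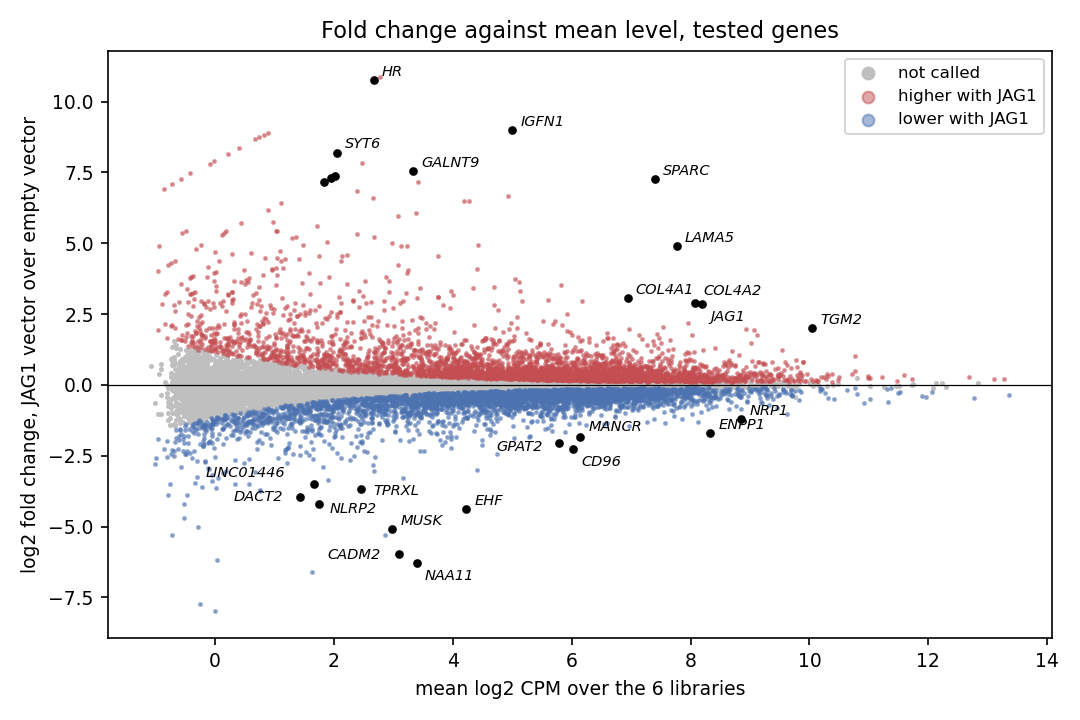
Log2 fold change (JAG1 vector over empty vector, vertical axis) against mean log2 CPM over the 6 libraries (horizontal axis) for 14304 tested genes, with 3787 called higher in red, 3667 called lower in blue and the others in grey; black points are JAG1 and the genes with the largest changes or the smallest p. SPARC and LAMA5 stand out among genes at high levels, and the fitted values at the top left, HR among them, rest on few or 0 control counts and depend on the prior count.

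Genes of cholesterol synthesis and uptake rose together. Of 22 tested, 18 rose, 1 fell and 3 were not called, with a median log2 fold change of 0.92, and the counts were the same adjusted over the list alone. The squalene synthase gene FDFT1 rose from 61.5 ± 2.93 to 163.9 ± 12.5 CPM (log2 fold change 1.41, SE 0.06, edgeR adjusted p = 8.40e-22), and SREBF2, which encodes a transcription factor of the pathway, from 154 ± 5.63 to 327 ± 10.8 CPM (1.09, SE 0.05). The member that fell, named after its value was seen, was PMVK (-0.36). The list was called by limma's camera (adjusted p = 1.30e-07) but not with an estimated correlation (adjusted p = 0.343 with an estimated correlation).

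Collagen and basement membrane genes were mostly higher. Of 25 tested, 16 rose, 4 fell and 5 were not called, the same adjusted over the list alone, with a median of 0.85. COL4A2 rose from 64.8 ± 4.56 to 475.5 ± 23.5 CPM (log2 fold change 2.87, SE 0.05, edgeR adjusted p = 4.17e-33) and COL4A1, its divergently transcribed neighbour, from 26.2 ± 2.74 to 218.3 ± 8.12 CPM (3.06, SE 0.06). Both lie on chromosome 13, where their neighbours had a median of 0.49. TGFBI rose by 1.96 and COL7A1, the collagen of anchoring fibrils, by 1.76. The 4 members that fell, named after their values were seen, were COL8A1, LAMA3, LAMB1 and LAMB3. The camera adjusted p was 0.000445, and the adjusted p = 0.313 with an estimated correlation.

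Antigen presentation genes were higher although the regional median of the list was -0.35. Of 20 tested, 14 rose, 2 fell and 4 were not called, and 14 rose and 3 fell adjusted over the list alone, with a median of 0.74. CD74, the invariant chain of MHC class II, rose from 16.5 ± 1.61 to 127.6 ± 4.20 CPM (log2 fold change 2.95, SE 0.07, edgeR adjusted p = 4.17e-29). The immunoproteasome gene PSMB9 rose by 2.81, HLA-DRA by 0.98 and B2M, the light chain of MHC class I, by 0.75. Of the PSMB9 span, 61.6% lies inside other genes. The 2 members that fell, named after their values were seen, were HLA-DMA and CD274, which encodes PD-L1. The camera adjusted p was 0.000476, and the adjusted p = 0.343 with an estimated correlation.

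Of 28 tested interferon response genes, 17 rose, 6 fell and 5 were not called, the same adjusted over the list alone, with a median of 0.54. The list held 36 genes. IFIT1, IFIT2, IFIT3, OAS2, OAS3 and RIGI had 0 counts in all libraries, and OAS1 and IRF9 had too few to be tested. The list test therefore says nothing about these members. The tetherin gene BST2 rose from 0.831 ± 0.179 to 15.5 ± 0.795 CPM (log2 fold change 4.22, SE 0.21), the antiviral GTPase genes MX1 and MX2 by 3.10 and 2.92, and PARP14 by 2.40, with neighbours at a median of 0.96. The members that fell, named after their values were seen, were RSAD2 (-1.53, from 55 to 20 counts), IFI44 (-1.30), IFI27 (-0.75), USP18 (-0.70), IRF7 (-0.62) and HERC5 (-0.56). The camera adjusted p was 0.00278, with adjusted p = 0.343 with an estimated correlation and 0.0679 when only genes with little overlap were kept, the 2 of 17 other settings in which it missed 0.05 (range 0.000132 to 0.343). Among 21 cytokine and NF-kB genes, 14 rose, 2 fell and 5 were not called, and 14 rose and 3 fell adjusted over the list alone, with a median of 0.58. IL1B rose from 1.03 ± 0.267 to 17.5 ± 1.37 CPM (4.07, SE 0.20), IL11 by 1.77 and CSF1 by 0.93. ICAM1 had 0 against 110 counts, at least 33.7-fold higher against 3 counts over the group, with 95.5% of its span inside other genes, and the median of the list is unaltered with ICAM1 at that bound. The members that fell, named after their values were seen, were IL24 and CXCL8. The camera adjusted p was 0.00334, and the adjusted p = 0.343 with an estimated correlation.

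Unfolded protein response genes were mostly higher, with 18 of 23 up, 1 down and 4 not called, the same adjusted over the list alone, and a median of 0.45. The chaperone genes HYOU1 and HSPA5 rose by 0.90 and 0.62, and TRIB3, a stress-induced pseudokinase gene, by 1.59. DNAJC3 rose by 0.84 on chromosome 13, with neighbours at a median of 0.53. The member that fell, named after its value was seen, was DNAJB9 (-0.54). The camera adjusted p was 0.000337, and the adjusted p = 0.343 with an estimated correlation. Of 35 cell cycle genes, 25 rose, 5 fell and 5 were not called, and 26 rose and 5 fell adjusted over the list alone, by a smaller median of 0.25. TYMS rose by 1.41 near the end of chromosome 18, where its neighbours had a median of 1.12. CCNB1 rose by 0.56, MCM6 by 0.54 and PLK1 by 0.46. The members that fell, named after their values were seen, were MKI67, MCM3, CCNE2, AURKB and BUB1. With the regional offset, 21 members rose and 0 fell. The camera adjusted p was 0.000692, and the adjusted p = 0.442 with an estimated correlation. These 7 lists, all upward, were the ones called among 30 tested, and with an estimated correlation camera called 0, with 3 at an unadjusted p under 0.05, while fry called 23.

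**Figure D3:**
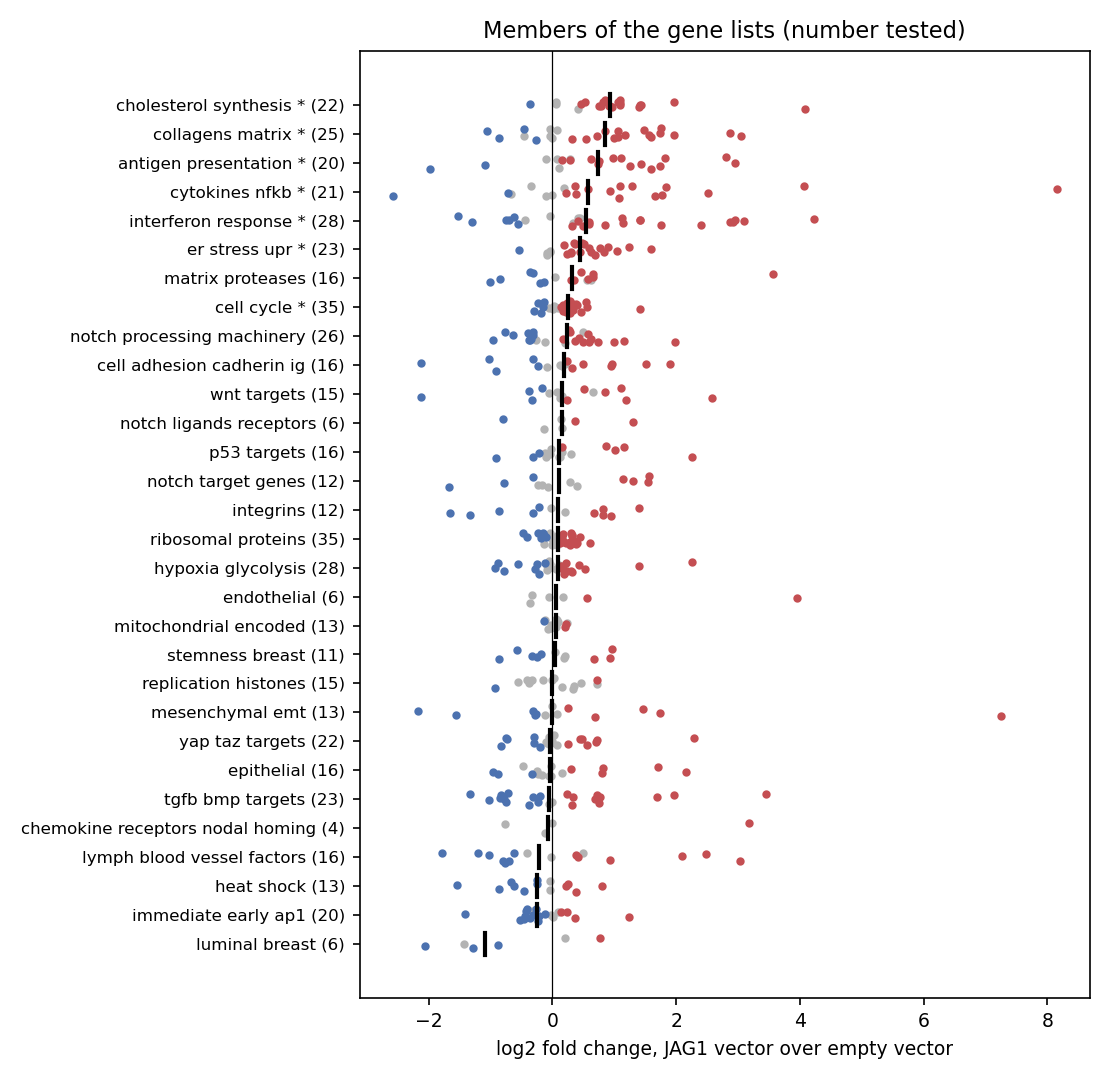
Log2 fold changes (JAG1 vector over empty vector, horizontal axis) of the tested members of 30 gene lists, 1 row per list with the number tested in brackets; red points rose, blue points fell, grey points were not called, black bars are medians and stars mark the 7 lists called by limma's camera. Medians run from -1.08 for luminal genes to 0.92 for cholesterol synthesis.

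Vessel growth factor genes went both ways, with 6 of 16 up, 7 down and 3 not called (camera adjusted p = 0.628; the same counts adjusted over the list alone). NRP1, a co-receptor for VEGF and semaphorins, fell from 646 ± 9.12 to 279 ± 4.96 CPM (log2 fold change -1.21, SE 0.04, edgeR adjusted p = 2.49e-24). VEGFC, the main growth factor of lymphatic vessels, fell by 1.78 from 38.3 ± 1.72 to 11.1 ± 1.01 CPM (SE 0.10, edgeR adjusted p = 8.31e-18), VEGFA by 0.77 and PDGFC by 0.81. Their neighbours were lower too, with medians of -0.42 for NRP1, -0.73 for VEGFC, -0.52 for VEGFA and -0.42 for PDGFC. The members that rose, named after their values were seen, were the receptor gene FLT4 (3.03, from 12 to 106 counts), PDGFB (2.49), VEGFD (2.10, from 21 to 98 counts), PGF (0.93), PDGFA (0.42) and VEGFB (0.39). Of 4 chemokine receptor genes tested, the atypical receptor gene ACKR3 rose by 3.18, from 0.280 ± 0.189 to 2.54 ± 0.237 CPM, and 3 were not called. Without control library 1 the rise of ACKR3 was 3.81, in a range from 2.76 to 3.81 when 1 library was left out. Values were -0.01 for CXCR4, -0.12 for CCR7 and -0.76 for CCR10 (camera adjusted p = 0.799; the median was negative, the mean and the test positive; the same counts adjusted over the list alone). Of the CCR10 span, 68.5% lies inside other genes.

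Mesenchymal genes were split, with 5 of 13 up, 5 down and 3 not called (camera adjusted p = 0.735, the same counts adjusted over the list alone). FN1 rose from 274.5 ± 10.6 to 755 ± 33.3 CPM and the transcription factor gene SNAI2 by 1.75, besides SPARC. VIM fell by 0.31, as did its neighbours on chromosome 10 (median -0.31), and with the regional offset its log2 fold change was 0.00. Epithelial genes counted 5 up, 3 down and 8 not called of 16 (camera adjusted p = 0.799, the same counts adjusted over the list alone), with KRT7 up by 2.17, KRT18 by 0.82, KRT8 by 0.80 and KRT19 down by 0.88. For mesenchymal and epithelial genes the median was slightly negative and the mean and test positive. Among 6 luminal genes 1 rose, 3 fell and 2 were not called, and 1 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.619). XBP1 rose by 0.77, SPDEF fell by 2.07 and FOXA1 by 1.29, which was not called without control library 1 (edgeR adjusted p = 0.0805; range over 18 other settings 0.000561 to 0.0805). Of 12 integrin genes 5 rose, 5 fell and 2 were not called (camera adjusted p = 0.775, the same counts adjusted over the list alone). ITGB4 rose by 1.40, ITGB5 by 0.96 and ITGA3 by 0.82, and ITGA2 fell by 1.34. The neighbours of ITGB5 had a median of 0.67, and with the regional offset its log2 fold change was 0.29.

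Of 16 matrix protease and inhibitor genes 7 rose, 6 fell and 3 were not called (camera adjusted p = 0.709), and 8 rose and 6 fell adjusted over the list alone. TIMP2 rose by 0.65 and SERPINE2 by 0.58, while ADAMTS1 fell by 1.01 and ADAMTS6 by 0.85. Of 16 adhesion genes 7 rose, 5 fell and 4 were not called (camera adjusted p = 0.691), and 7 rose and 6 fell adjusted over the list alone. MCAM rose by 1.51, L1CAM by 0.95 and CDH4 by 0.50, and CNTN1 fell by 2.12. The neighbours of L1CAM near the end of the X chromosome had a median of -0.65, and with the regional offset its log2 fold change was 1.61. Of the L1CAM span, 56.6% lies inside other genes. TGF-beta and BMP genes counted 10 up, 11 down and 2 not called of 23 (camera adjusted p = 0.917; the median and the test negative, the mean positive; the same counts adjusted over the list alone). INHBA, the activin subunit gene, rose by 3.46 and LTBP3 by 1.69, and the receptor gene TGFBR2 fell by 0.84. Wnt genes counted 6 up, 4 down and 5 not called of 15, and 7 up and 4 down adjusted over the list alone (camera adjusted p = 0.30). NKD1 rose by 2.58, FZD2 by 1.19 and WNT5A by 1.11, and FZD8 fell by 2.12.

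Among 20 immediate early and ERK-responsive genes 4 rose, 12 fell and 4 were not called, the same adjusted over the list alone, with a median of -0.25 (camera adjusted p = 0.108). EGR1 fell by 1.42, from 14.9 ± 2.12 to 5.59 ± 0.887 CPM, DUSP5 by 0.52, DUSP6 by 0.44 and SPRY4 by 0.36. The neighbours of SPRY4 had a median of -0.36, and it was not called with the regional offset. YAP and TAZ targets counted 7 up, 6 down and 9 not called of 22 (camera adjusted p = 0.969; the median and the test negative, the mean positive). NUAK2 rose by 2.29 and AMOTL2 by 0.71, and CCN2 fell by 0.74 and ANKRD1 by 0.73. Of 28 hypoxia and glycolysis genes 12 rose, 8 fell and 8 were not called (camera adjusted p = 0.775), with CA9 up by 2.25, ADM up by 1.40, BNIP3 down by 0.93 and HK2 down by 0.78. Of 16 p53 targets 5 rose, 3 fell and 8 were not called (camera adjusted p = 0.691). PHLDA3 rose by 2.26, GDF15 by 1.16 and BBC3 by 0.86, and CDKN1A fell by 0.91, with neighbours at -0.59. Of 11 stem cell genes 3 rose, 5 fell and 3 were not called (camera adjusted p = 0.881; the median and mean positive, the test negative), with MSI1 up by 0.94, ITGA6 up by 0.68, CD24 down by 0.87 and BMI1, with 81.3% of its span inside other genes, down by 0.57. In these last 4 lists, the counts were the same adjusted over the list alone.

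Heat shock genes counted 4 up, 7 down and 2 not called of 13 (camera adjusted p = 0.475, the same counts adjusted over the list alone). HSPH1, on chromosome 13 with neighbours at 0.58, rose by 0.80, while HSPA1B fell by 0.86, DNAJB1 by 0.68 and HSP90AA1 by 0.47. Of the DNAJB1 span 94.9% lies inside other genes, and of the HSPA1B span 56.5%. The neighbours of HSPA1B had a median of -0.47. The neighbours of HSP90AA1 on chromosome 14 had a median of -0.56, and with the regional offset its log2 fold change was 0.09 and not called. Of 35 ribosomal protein genes 17 rose, 7 fell and 11 were not called (camera adjusted p = 0.108, the same counts adjusted over the list alone), with RPS3 up by 0.62, RPL13 by 0.44, RPS6 by 0.40 and RPL4 by 0.38. With the regional offset, 24 rose and 0 fell, and the list was called (camera adjusted p = 0.000182), but not when the offset was joined with an estimated correlation (0.831). It was also called without control library 2 (0.0427), without rescue library 2 (0.0446) and with fry (0.0424; range over 17 other settings 0.000182 to 0.868). Replication histone genes counted 1 up (H2AC6, 0.72), 1 down (H3C2, -0.93) and 13 not called of 15, with values of 0.46 for H2BC5 and -0.41 for H1-4 (camera adjusted p = 0.881). Of the H2BC5 span, 80.0% lies inside other genes. Adjusted over the list alone, 1 rose and 0 fell, and the adjusted p of H3C2 missed 0.05 in 5 of 17 other settings (range 0.00693 to 0.183), the omission of control library 2 (0.0874), rescue library 2 (0.0976) or rescue library 3 (0.0581) among them. H2BC5 was called without control library 2 (edgeR adjusted p = 0.0142), without rescue library 2 (0.0457) and with the regional offset (0.00338; range over 17 other settings 0.00338 to 0.410).

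Signs of other cells and of RNA quality were looked for with the same lists. Mitochondrially encoded genes took 5.21 to 5.95% of counts across the 6 libraries, and the 10 most abundant genes 6.49 to 7.22%. Of 13 mitochondrial genes 2 rose (MT-ND4, 0.22, and MT-CO1, 0.20), 1 fell (MT-ND1, -0.13) and 10 were not called, MT-ND4L with 0.24 among them (camera adjusted p = 0.799). Adjusted over the list alone 2 rose and 0 fell, and the 3 calls were absent with DESeq2 (adjusted p = 0.0703, 0.0730 and 0.256; range over the 18 other settings of the 3 genes 6.27e-08 to 0.256). The call of MT-ND1 was also absent without control library 2 (0.0645), control library 3 (0.103), rescue library 1 (0.113) or rescue library 2 (0.141), and that of MT-ND4 without control library 2 (0.0572). MT-ND4L was called in 6 of 18 other settings, the omission of rescue library 2 (3.68e-05) or 3 (0.00705) among them (range 3.68e-05 to 0.136). A single leukocyte gene had enough counts, CD14, which rose from 30 to 91 counts or from 0.580 ± 0.132 to 1.65 ± 0.453 CPM (edgeR adjusted p = 0.00439). LIN28B was the tested gene of those chosen for HEK293T packaging cells (0.25, edgeR adjusted p = 0.0830, called adjusted over the list alone), and it was called with the regional offset, at 0.47 (edgeR adjusted p = 0.00140; range over 18 other settings 0.00140 to 0.247). With 1 tested gene each, these 2 lists had no list test. Of 6 endothelial genes the receptor gene TIE1 rose by 3.96, from 17 to 286 counts, and EGFL7 by 0.56, and 4 were not called, with values of -0.33 for PECAM1 and -0.37 for PROX1 (camera adjusted p = 0.691, the same counts adjusted over the list alone). PECAM1 was called without rescue library 2, at -0.50 (edgeR adjusted p = 0.0174; range over 18 other settings 0.0174 to 0.431), and PROX1 with the regional offset, at -0.69 (0.0153; range over 17 other settings 0.0153 to 0.475).

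Fold changes also followed position in the genome. The median log2 fold change was 0.57 over 191 expressed genes of chromosome 13, 88.5% of which were higher in the rescue group, and -0.45 over 399 genes of chromosome 4, 79.7% of which were lower. Chromosomes 6 and 14 had medians of -0.36 each, over 543 and 346 genes, with 82.9% and 82.4% lower. The permutation p was 1e-04 for each of these 4 chromosomes, the smallest that 10000 permutations can give (adjusted 0.000153), and 17 of 23 chromosomes had an adjusted permutation p under 0.05. The permutation treats genes as independent, but neighbouring genes correlated (Spearman 0.345, against at most 0.179 when shuffled within chromosomes). These p-values are therefore likely too small, above all for chromosomes with small medians such as X (0.06). All 9 pairs of a rescue and a control library gave a median for chromosome 13 between 0.53 and 0.63 and for chromosome 4 between -0.46 and -0.37. The shifts were uneven along chromosomes 4, 6 and 14. On chromosome 4, windows of 10 Mb between 80 and 150 Mb had medians from -0.15 to 0.00, and those on either side from -0.70 to -0.43. On chromosome 6, windows before 80 Mb had medians from -0.73 to -0.36, and those from 80 Mb on from -0.30 to -0.05. On chromosome 14, windows from 20 to 30 Mb and from 30 to 40 Mb had -0.07 and -0.19, and later ones from -0.55 to -0.33. Windows with under 15 genes were left out. Parts of other chromosomes were shifted too. The first 20 Mb of chromosome 18, which hold TYMS, had a median of 1.05 over 49 genes, against 0.08 for the rest of that chromosome. The X chromosome from 150 Mb had -0.60 over 51 genes against 0.11, and the first 10 Mb of chromosome 17 had -0.40 over 109 genes against 0.06. These segments were chosen after their values were seen. Chromosome of origin accounted for 11.4% of the variance of log2 fold changes limited to 2 in size.

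**Figure D4:**
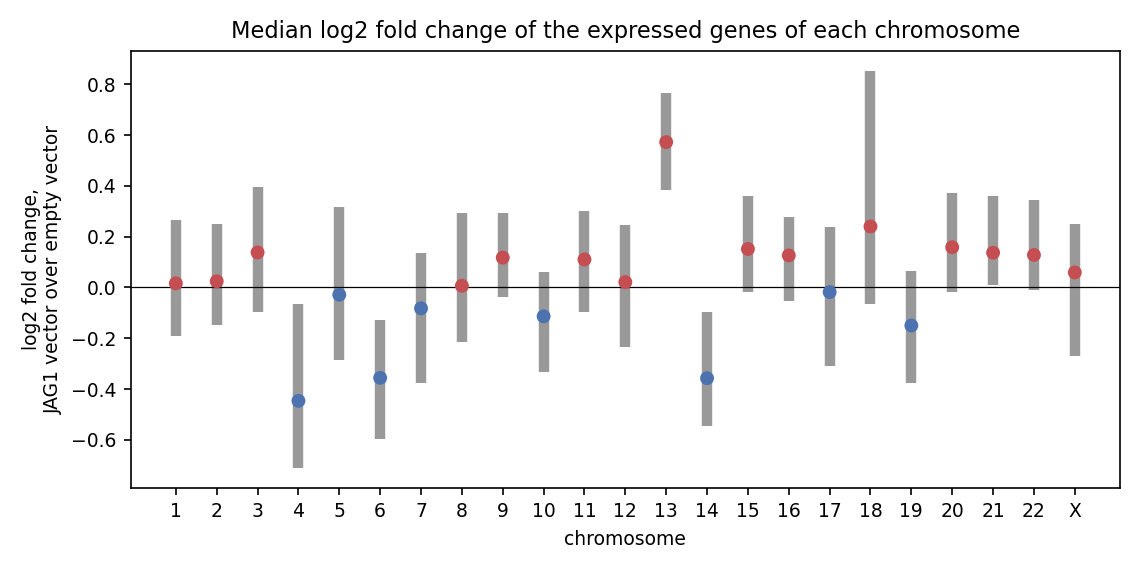
Median log2 fold change (JAG1 vector over empty vector, vertical axis) of the expressed genes of each chromosome (horizontal axis), as points, red above 0 and blue below 0, with grey bars from the lower to the upper quartile of its genes. Chromosome 13 has the highest median at 0.57 and chromosome 4 the lowest at -0.45.

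The labels name 1 knockout line with each vector, so any difference between the 2 cell populations other than the vector enters the same comparison. With a test against a fold of 1.2 in place of any change, 4140 genes were called.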

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

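The regional offset and the restriction to genes with little overlap were chosen after the results were seen; the other settings were not. Over 22 settings, JAG1 was higher in the rescue group wherever it was tested, with log2 fold changes from 2.80 to 2.89 when 1 library was left out. The count of called genes (7454) was 6892 to 7153 without 1 library, with 7 or 8 lists called, 6774 with DESeq2, 6082 at an adjusted p under 0.01, 6123 with the regional offset and 5496 of 10006 genes with little overlap. The share of calls that were higher went from 50.8% to 46.2% with library size only. A test against a fold of 1.2 called 4140 genes, 2058 higher and 2082 lower, fewer because small changes do not pass it. Of the 7 lists, 0 were called with an estimated correlation, and fry, which does not compare a list with other genes, called 23. The estimated version has few degrees of freedom with 6 libraries, so its missing calls decide little on their own. Estimated correlations of the 7 lists ran from -0.026 for collagens to 0.249 for cholesterol synthesis, against the preset 0.01. Where the estimate lies above the preset, the preset p-values are likely too small. Of 2546 values for 144 named genes, 2499 kept direction and side of the threshold, 24 lost the call, 15 gained it and 8 changed sign. Of 507 list values, 457 kept both, 8 lost the call, 18 gained it and 24 changed sign. Among those that changed sign, VIM and HSP90AA1 alone had been called, and both changed with the regional offset, which subtracts the shift of their neighbours. With that offset NOTCH1 and NOTCH4 changed sign by the same subtraction. Their neighbours had medians of 0.18 and -0.46, against main log2 fold changes of 0.16 and -0.14. For the other changes of sign the cause was not tested. With the regional offset, log2 fold changes were -0.026 for NOTCH1, 0.31 for NOTCH4, 0.0012 for VIM and 0.090 for HSP90AA1. Without 1 library they ran from -0.42 to 0.14 for NOTCH4, from -0.30 to 0.18 for CCR7 and from -0.079 to 0.036 for CXCR4. For lists whose camera direction changed, the adjusted p without 1 library ran from 0.885 to 0.972 for YAP and TAZ targets, from 0.789 to 0.981 for TGF-beta and BMP genes and from 0.514 to 0.972 for mitochondrial genes. It was 0.957 for stem cell genes with no filter on low counts and 0.978 for histone genes among protein-coding genes only. With fry it was 0.833 for YAP and TAZ targets and 0.0131 for TGF-beta and BMP genes. With the regional offset it was 0.903 for chemokine receptors, 0.808 for YAP and TAZ targets, 0.906 for stem cell genes, 0.519 for histones and 0.965 for heat shock genes. With little overlap it was 0.897 for epithelial, integrin and adhesion genes, 0.993 for proteases and for TGF-beta and BMP genes, and 0.979 for p53 targets. The replicate numbers did not pair the libraries, with correlations of 0.0161, -0.0256 and -0.014 between deviations of libraries with the same number, and only libraries with number 1 matched best with their own number. With the replicate number as a block, 7304 genes and 7 lists were called, and the direction changed for YAP and TAZ targets (adjusted p = 0.998), TGF-beta and BMP genes (0.9995) and stem cell genes (0.9995). Depth limits genes at low levels, where 3 counts are 0.150 to 0.190 CPM.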

Other observations

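The tests of a gain on chromosome 6 and of leukocytes for the antigen presentation genes, the regional offset and the search for genes counted in 1 group were chosen after the results were seen. Some genes had 0 counts in all 3 libraries of one group and at least 10 in each library of the other. There were 18 with reads in the rescue group alone and 2 in the control group alone, and 13 and 2 of these had under 10% of their span inside another gene. Besides HR, they included KRT5, a keratin gene of basal epithelium, with 60, 80 and 36 counts in rescue libraries 1 to 3, and the adhesion receptor gene ADGRE1 with 60, 66 and 57. The calsyntenin gene CLSTN2 had 165 counts in total, ASTN1, which encodes the neuronal protein astrotactin 1, had 157 and ARAP2, a GTPase regulator gene, had 128. The noncoding RNA LINC01626 had 24, 45 and 24 counts in control libraries 1 to 3 and 0 in the rescue libraries. No such gene was found in the other 9 splits of the 6 libraries into 3 and 3, where the highest number was 0. Those splits have libraries of both groups on either side, so such genes were unlikely there in advance and nothing is concluded from their absence.

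Long stretches of chromosomes were shifted between the groups, upward on 13 and downward on 4, 6 and 14. After regression on GC content, gene length and mean expression, with GC values for 99.7% of genes, the medians of chromosomes 13 and 4 still differed by 0.994 (95% interval 0.928 to 1.05) against 1.02 before, which argues against such a bias. The interval resamples genes as if they were independent and is likely too narrow. A single odd library is argued against by the lowest difference over the 9 pairs of libraries, 0.959. Both tests used chromosomes 13 and 4, which had the highest and the lowest median in these same genes, and did not cover the others. A difference in DNA copy number between the 2 cell populations predicts that genes at low, middle and high expression shift alike. The smallest median among these classes on the 4 chromosomes was 0.308 in the direction of the shift. From low to high expression, medians went from 0.48 to 0.65 on chromosome 13 and from -0.31 to -0.41 on chromosome 6, without such an order on 4 and 14. These chromosomes were chosen by their medians in the same genes, so a shift in every class was likely in advance. The result cannot tell copy number from other causes that cover long stretches, and copy number stays a hypothesis. No DNA data were analysed here, and an effect of JAG1 on long stretches of chromosomes stays open as untested.

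Antigen presentation genes were higher although most of the tested members lie on chromosome 6, which was lower. The 14 members there had a median of 0.80, with 10 called higher and 1 lower, while the other 97 tested genes between the first and the last of them had a median of -0.48 (95% interval -0.56 to -0.38), which argues against a gain of DNA over that stretch. This interval too resamples genes as if they were independent and is likely too narrow. The leukocyte gene CD14 was called higher, and 14 leukocyte markers with it had 195 counts in the rescue group and 114 in the control. Their upper 95% limit in the rescue group was 4.08 CPM against a rise of CD74 by 111 CPM, and the general leukocyte gene PTPRC had 4 counts against 8 in the control, which argues against leukocytes as the whole source. ADGRE1, a gene also expressed by myeloid cells, was not among the markers and had 183 counts in the rescue group and 0 in the control. Reads shared between HLA genes and differences between the populations other than the vector were not tested, and an effect of JAG1 stays open.

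Regional shifts were weighed as the whole cause of the 7454 calls. With each gene offset by its regional median, 6123 genes (42.8%) were called, which argues against a shift shared equally by neighbouring genes as the whole cause. The offset was entered without its own error, so some of these calls may come from it. Genes may also follow a regional shift unequally, which the offset cannot remove. Of the first calls, 4824 were called in the same direction, 185 in the opposite one and 2445 no longer, while 1114 genes were called only with the offset. The number changed at least 2-fold went from 1547 to 1307. What remains may come from JAG1 or from other differences between the populations, which the design does not separate.

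The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 7454 genes, 1547 of them changed at least 2-fold, and 7 lists, and it was the 1 split with as many in each case. Among the other splits, edgeR called at most 0 genes, with at most 134 at an unadjusted p under 0.05, and camera at most 5 lists. Each of those splits has libraries of both groups on either side, so the difference between the groups widens the spread and hinders calls. They therefore do not show how many calls arise without a difference.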
